A study of Drosophila melanogaster with 30 samples.

How the data were processed

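Whole brains of virgin Canton-S female flies were profiled on Affymetrix Drosophila Genome 1.0 arrays, 30 in all: 21 from a sleep deprivation experiment with 7 groups and 9 from an active period experiment with 3 groups, with 3 arrays per group. Flies were housed at 50 per vial with 12 h of light at 25 °C, per the labels' protocols, and were killed in hot water before the brains were dissected. The deposited values are log2 expression values made by the authors with the robust multi-array average (RMA), which corrects background, normalises quantiles over arrays and gives 1 value per probe set, per the series' design text. The submitters' processing notes name the affy package and RMA, and their versions are not given in the sources used here. Whether both experiments were normalised in a single run is not stated, so every difference between groups was taken within an experiment. Quantile normalisation holds the spread of all arrays nearly alike, so a shift shared by most transcripts would not be seen, and differences near the dim end are compressed. The deposited scanner settings gave the chip lot and scan day of each array and, for the 21 arrays of the deprivation experiment, a hybridisation date. Arrays that share this date and time are called a wash run here, although the field names hybridisation and not washing. Lots, days and runs were used as batches. No wash run was read for the 9 active period arrays, so their comparisons were not tested for it.

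Of 14010 probe sets, 44 controls were left out of the tests and 13966 were tested. The platform annotation pairs 12443 of them with 1 gene symbol, 327 with several and 1196 with none. Symbols were updated through the gene number in the RefSeq table of the Release 6 plus ISO1 MT assembly, used for names only; 12394 matched and 49 kept the platform's symbol. The named probe sets cover 10844 genes, of which 1209 have more than 1 probe set. Probe sets with several or no symbols are counted and not named.

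Samples were grouped by their titles. Differences were fitted with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes) on the deposited values, with 1 mean per group, over the arrays of each experiment, and p-values were adjusted by Benjamini and Hochberg over all probe sets, with a threshold of 0.05. Tests were the mean of the matched differences at 2, 4 and 6 h, a moderated F test of those 3 differences, each difference by itself, linear trends from ZT14, the change of the effect from 2 to 6 h, stimulated minus wake flies, and wake flies at ZT14 minus flies at ZT10. The 4 h deprivation effect was set against the stimulation effect in 1 fit of all 30 arrays. As in the study's text, stimulation was also tested within the deprivation set at an unadjusted p of 0.01. The study's Fs test was run with 100 permutations of residuals, where the study's text states 1000, and Storey q-values. These p-values measure the spread between the pools of each group.

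Comparisons, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The rule named, for the mean over 2, 4 and 6 h, the 12 largest rises and the 12 largest falls past the threshold with 1 sign at all 3 times, up to 5 rises and 5 falls in the other comparisons, the 5 smallest p-values where none passed, and up to 4 members per list by p. In the mean it also named every antimicrobial peptide, core clock and heat shock gene past the threshold. Other members are named where the count of a list adjusted alone calls for it. The 34 lists hold 25 pathways or families and 9 sets of markers of other cells that a dissected brain could carry along. Each gene entered list tests with 1 probe set, the brightest. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 34 lists; "adjusted over the list alone" means Benjamini and Hochberg within the members of a list. Fry tests whether the genes of a list move, on balance, in 1 direction, and does not compare the list with other genes.

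Alternatives were the omission of the dimmer probe sets, renewed quantile normalisation, median centring, fits of only the groups compared or of all 30 arrays, array weights, trended and robust variance, blocks for replicate number, chip lot and wash run, 1 probe set per gene, the Fs test, a threshold of 0.10 and the omission of each array. Cyclic loess, a covariate for the 3' to 5' control difference, the omission of wash run 4 and, for the gene lists, the chip lot and wash run blocks were added later. Relabelling tests of array measures were exact and two-sided, within each time for the deprivation experiment.

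The fits were tested on simulated data with known changes in 13966 probe sets. Errors were normal and independent, with means and SDs from the real arrays. No batch and no correlation between probe sets was simulated, so recovery in the real arrays may differ. An added change of 0.5 log2 units was recovered for 95.0% of changed probe sets in the mean over 2, 4 and 6 h, for 80.0%, 84.0% and 77.0% at 2, 4 and 6 h, for 70.0% in stimulated minus wake flies and for 74.0% in wake flies at ZT14 minus ZT10. For the change from 2 to 6 h it was 44.0%. Trends of 0.1 per hour were recovered for 90.0% in sleeping and 89.0% in deprived flies. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 drew the figures. Probe-level intensities were not used here.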

Results

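Gene expression was measured in whole brains of virgin Canton-S females, a standard wild-type strain of Drosophila, at 5 days of age. RNA came from pools of 139 to 193 dissected brains and was hybridised to Affymetrix Drosophila Genome 1.0 arrays, with 3 arrays in each of 10 groups. In the sleep deprivation experiment (21 arrays), flies were kept awake for 2, 4 or 6 h from ZT14, where ZT counts hours from lights-on and ZT14 is the start of consolidated sleep. Undisturbed flies were killed at the same hours, and a further group was taken at ZT14 as the 0 h point. In the active period experiment (9 arrays), flies were stimulated by hand from ZT10 to ZT14, when they are normally awake, and were compared with undisturbed wake flies of the same hour; a group taken at ZT10 gave the start. Array medians lay between 4.88 and 4.96 log2 units, and arrays of a group correlated between 0.974 and 0.997 across probe sets. The number of arrays limits the precision of every value. The submitters call the 3 arrays of a group biological replications, and each holds its own pool. The labels of sleeping 6 h replicate 1 conflict: its source name says deprived, while its title, description and condition say sleeping, and it was grouped as sleeping. In the deprivation experiment the difference between 3' and 5' control signal was largest in deprived 2 h replicate 2, at 2.70 log2 units for actin, and sleeping 2 h replicate 2, at 2.52, against a mean of 2.16 over the deprived arrays.

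The first comparison asked which transcripts differ between deprived and sleeping brains at matched times. The largest named rise was in sr, which encodes a zinc finger transcription factor of the EGR family. Its signal was 1.61 ± 0.0941 log2 units higher (SE; 3.05-fold; adjusted p = 6.09e-09) as a mean over 2, 4 and 6 h. It was higher in 9 of 9 deprived arrays than the mean of the sleeping arrays of that hour, and counts out of 9 below are made in this way. The genes were chosen on these same arrays, so such counts are no independent support. CG13315 rose by 0.99 ± 0.125 (adjusted p = 0.000453) and aay, which encodes a phosphoserine phosphatase, by 0.69 ± 0.0835 (adjusted p = 0.000297), each in 9 of 9 deprived arrays. Genes of the humoral immune response rose with them. Mtk, the antimicrobial peptide metchnikowin, rose by 0.91 ± 0.183 (adjusted p = 0.0189; 9 of 9). The bomanins BomS2, BomBc3 and BomS5, secreted peptides of the Toll response, rose by 0.83, 0.63 and 0.58 (adjusted p = 0.0216, 0.0268 and 0.0447; at least 8 of 9). The largest named falls were in chaperone genes. DnaJ-1, an Hsp40 co-chaperone, fell by 0.77 ± 0.110 (adjusted p = 0.00115) and CG1416, related to activators of the Hsp90 ATPase, fell by 0.68 ± 0.119 (adjusted p = 0.00760). Stip1, which links Hsp70 to Hsp90, fell by 0.62 ± 0.118 (adjusted p = 0.0142), and all 3 were lower in 9 of 9 deprived arrays.

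Further rises were in CG5966 (0.77, adjusted p = 0.0180), CG16978 (0.60, adjusted p = 0.00115), CG16926 (0.60, adjusted p = 0.0283), CG16772 (0.59, adjusted p = 0.00115) and CG1572 (0.58, adjusted p = 0.000560), in at least 8 of 9 deprived arrays. Among the falls were CAH7, named as a carbonic anhydrase (-0.45 ± 0.0649, adjusted p = 0.00115), and fne, a neuronal RNA-binding protein of the Elav family (-0.42 ± 0.0749, adjusted p = 0.00825). Akap200, an anchoring protein of protein kinase A (-0.45 ± 0.0858, adjusted p = 0.0140), and RhoGAP102A (-0.41 ± 0.0765, adjusted p = 0.0125) fell as well. CG7135 (-0.43, adjusted p = 0.00315), Cyp6g1, a cytochrome P450 of insecticide metabolism (-0.48, adjusted p = 0.0224), and CG14400 (-0.48, adjusted p = 0.0354) fell too. So did sov (-0.45, adjusted p = 0.0428) and apolpp, the precursor of the lipophorin lipoproteins (-0.52, adjusted p = 0.0269), and each of these falls was seen in at least 8 of 9 deprived arrays. A further apolpp probe set gave -0.27 (adjusted p = 0.305). These 24 genes are the 12 largest rises and 12 largest falls with 1 sign at 2, 4 and 6 h.

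In limma, 129 of 13966 probe sets passed an adjusted p of 0.05, 68 higher and 61 lower in deprived brains, and they covered 105 named genes. An F test for a difference at any of the 3 times called 31 probe sets, 21 higher and 10 lower on average. The study's text gives 252 genes at a false discovery rate of 5% and 578 at 10%; the Fs test run here, with shrunken variances and permuted residuals, called 87 and 147 probe sets for a difference at any time and 145 and 282 for the mean. At 2 and 6 h every deprived array belonged to another wash run than the sleeping arrays of that hour. With wash run as a block 72 probe sets passed, of which 49 were among the 129, and all 129 kept their sign. Of the 24 genes named by size 11 still passed, namely sr, CG13315, aay, CG16772, CG1572, RhoGAP102A, fne, CAH7, Stip1, CG1416 and DnaJ-1. Under that block Mtk stood at 0.68 (adjusted p = 0.0972) and BomS2 at 0.87 (adjusted p = 0.137). The 129 were chosen on these same arrays, so their signs within a batch are no independent test. Within each of chip lots 2 and 3, 129 had the same sign. Within wash runs 2 and 3, whose deprived and sleeping arrays differ in hour, 127 and 126 did, and among the 4 h arrays of wash run 2, 125. Without the 4 arrays of wash run 4, all deprived, 58 passed, and the lowest count without a single array was 66, reached without sleeping 4 h replicate 1.

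**Figure D1:**
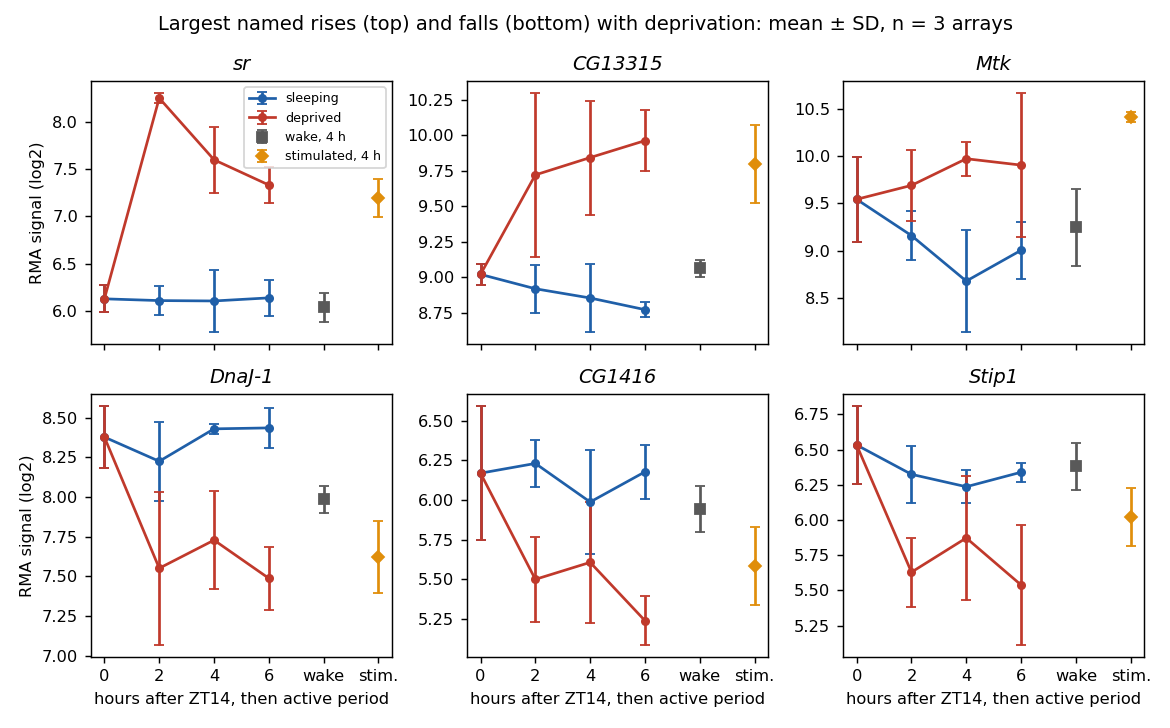
RMA signal (log2; mean and SD of 3 arrays) of the 3 largest named rises and 3 largest named falls, against hours after ZT14 for sleeping and deprived flies and for wake and stimulated flies of the active period. The signal of sr stood at 8.25, 7.60 and 7.33 in deprived flies at 2, 4 and 6 h against 6.11, 6.11 and 6.14 in sleeping flies, and at 7.20 in stimulated against 6.04 in wake flies.

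The fixed lists of genes were then tested as groups. Of 17 activity-regulated and immediate early genes, 3 rose, 14 did not pass and 5 were higher when adjusted over the list alone. Those that rose were sr, CG17778 (0.55, adjusted p = 0.00173) and puc, a phosphatase of JNK signalling (0.37, adjusted p = 0.0456). CG14186 stood at 0.70 (adjusted p = 0.0513). The list as a whole was higher (camera adjusted p = 1.10e-05; adjusted p = 0.0708 with an estimated correlation). All 8 antimicrobial peptide genes had a positive difference, with a median of 0.41. Mtk rose, the other 7 did not pass, and 5 were higher when adjusted over the list alone; DptB stood at 0.91 (adjusted p = 0.107), Drs at 0.77 (adjusted p = 0.275) and Drsl5 at 0.60 (adjusted p = 0.166). The camera adjusted p of the list was 5.82e-05, and the adjusted p was 0.203 with an estimated correlation. With wash run as a block its median was 0.20. It was 0.19 and 0.54 within chip lots 2 and 3. Within wash runs 2 and 3, at unmatched hours, it was 0.32 and 0.09, and among the 4 h arrays of wash run 2 it was 0.12.

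Of 29 genes of immune recognition and signalling, 2 rose and 5 were higher when adjusted over the list alone. Rel, the NF-kappaB factor of the Imd pathway, rose by 0.39 ± 0.0677 (adjusted p = 0.00760; 9 of 9 deprived arrays), and BomS2 was the other. The inhibitor cact (0.19, adjusted p = 0.0686) and the peptidoglycan recognition protein gene PGRP-LB (0.21, adjusted p = 0.0710) did not pass. The camera adjusted p of the list was 0.00711, against an adjusted p of 0.505 with an estimated correlation. Of 55 circulating and secreted proteases and serpins, 3 rose and 8 were higher when adjusted over the list alone (camera adjusted p = 4.02e-05; adjusted p = 0.505 with an estimated correlation). The 3 were the serpins Spn88Eb (0.40, adjusted p = 0.0216), Spn28Dc (0.29, adjusted p = 0.0302) and Spn27A, an inhibitor in the melanisation and Toll cascades (0.23, adjusted p = 0.0417). The protease Sp7 stood at 0.23 (adjusted p = 0.0697). Of 83 cytochrome P450 genes, Cyp6a8 (0.31, adjusted p = 0.0204) and Cyp4ac3 (0.38, adjusted p = 0.0428) rose and Cyp6g1 fell, with 3 higher and 1 lower when adjusted over the list alone. As a group they were higher (camera adjusted p = 0.0177; adjusted p = 0.580 with an estimated correlation). None of 45 genes of glutathione transfer and oxidative stress defence passed, and none when adjusted over the list alone, with GstD1 at 0.25 (adjusted p = 0.131) and Gclm at -0.31 (adjusted p = 0.108). Their list was higher (camera adjusted p = 0.00815; adjusted p = 0.537 with an estimated correlation). Lip4, a lipase, rose by 0.32 (adjusted p = 0.0189) among 22 lipid metabolism genes, of which fabp and bgm were lower when adjusted over the list alone, and that list did not pass (camera adjusted p = 0.689).

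Lower lists included cytosolic heat shock proteins, aminoacyl-tRNA synthetases, ribosome biogenesis and translation factors, while cytosolic ribosomal proteins (median 0.03) and endoplasmic reticulum chaperones (median -0.01) did not pass. Of 12 cytosolic heat shock protein genes, 2 fell, DnaJ-1 and the DnaJ-domain gene Droj2 (-0.32, adjusted p = 0.0272; 9 of 9 deprived arrays), and 3 were lower when adjusted over the list alone. Hsp60A, which was in the fixed list although it encodes a mitochondrial chaperonin, stood at -0.27 (adjusted p = 0.0845). The median was -0.12, and the list was lower (camera adjusted p = 0.00561; adjusted p = 0.203 with an estimated correlation). Stip1 and Hsp110 are not among the 12, having been listed under older symbols that matched no probe set. Of 30 aminoacyl-tRNA synthetase genes, LysRS (-0.26, adjusted p = 0.0218) and GlyRS (-0.23, adjusted p = 0.0285) fell, each in 9 of 9 deprived arrays, and 4 were lower when adjusted over the list alone. A negative difference was found for 27 of them, and the list was lower (camera adjusted p = 9.64e-05; adjusted p = 0.168 with an estimated correlation). Of 22 ribosome biogenesis genes none passed and 5 were lower when adjusted over the list alone, among them vito (-0.18, adjusted p = 0.0831), Non1 (-0.18, adjusted p = 0.126) and Ns2 (-0.19, adjusted p = 0.149). This list too was lower (camera adjusted p = 0.000151, and adjusted p = 0.168 with an estimated correlation). Within chip lots 2 and 3 and wash runs 2 and 3 the medians of this list and the synthetase list were negative. Among the 4 h arrays of wash run 2, with 1 deprived and 2 sleeping arrays, both were 0.02. Of 45 translation initiation and elongation factors none passed under either adjustment, with eEF1alpha2 at -0.54 (adjusted p = 0.186); the list was lower (camera adjusted p = 0.00711; adjusted p = 0.537 with an estimated correlation). Mitochondrial ribosomal proteins had a median of -0.0210 over 64 genes, and none passed. The camera adjusted p of the list was 0.0219, and the adjusted p was 0.874 with an estimated correlation. Random lists of genes matched in signal level had a median of -0.0259, so this list was not lower than genes of like level.

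The synaptic, channel, receptor and fly sleep lists were lower by small amounts, while neuropeptides had a median of 0.02. With the 3' to 5' control difference as a covariate these 4 calls ended (adjusted p = 0.624, 0.797, 0.624 and 0.533), with medians between -0.02 and -0.01. Their calls held in 6, 3, 2 and 4 of 10 other settings. None of 25 genes of synaptic vesicle release and recycling passed under either adjustment, and 20 had a negative difference. Syn, the synapsin gene, stood at -0.57 (adjusted p = 0.234) and nSyb, the neuronal synaptobrevin gene, at -0.48 (adjusted p = 0.262). The group was lower (camera adjusted p = 0.00762; adjusted p = 0.604 with an estimated correlation). Of 32 ion channels and pumps, Irk2, an inward rectifier potassium channel, fell (-0.28, adjusted p = 0.0420; 7 of 9 deprived arrays), and no other was lower when adjusted over the list alone. The channel list was lower (camera adjusted p = 0.0368; adjusted p = 0.580 with an estimated correlation). None of 34 neurotransmitter receptor genes passed, with nAChRalpha7 at -0.33 (adjusted p = 0.109), while the list was lower (camera adjusted p = 0.0242; adjusted p = 0.580 with an estimated correlation). Among 35 genes with published roles in fly sleep none passed over all genes, 2 were lower when adjusted over the list alone, namely fabp (-0.32, adjusted p = 0.111) and bgm (-0.46, adjusted p = 0.127). As a list they were lower (camera adjusted p = 0.0130; adjusted p = 0.537 with an estimated correlation). No core clock gene passed: of 14, slmb stood at -0.34 (adjusted p = 0.270), cwo at 0.23 (adjusted p = 0.286) and tim at -0.19 (adjusted p = 0.317), and the list did not pass (camera adjusted p = 0.175). The amino acid transporter gene mnd fell by 0.23 (adjusted p = 0.0420) within the insulin and nutrient signalling list, whose median (0.02) was positive while its test pointed down (camera adjusted p = 0.947). Oxidative phosphorylation (0.0695), calcium signalling (0.120), cytosolic ribosomal proteins (0.280), endoplasmic reticulum chaperones (0.601), neuropeptides (0.789), glycolysis (0.789) and proteasome subunits (0.815) had camera adjusted p-values above the threshold.

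Markers of tissue around the brain were tested in the same way. The lists of antennal and chemosensory markers (119 genes, median 0.06), trachea and cuticle markers (81 genes, median 0.06), muscle markers (19 genes, median 0.08) and ovary and germline markers (21 genes, median 0.06) were higher. In that order the camera adjusted p was 1.46e-05, 4.02e-05, 0.0130 and 0.0368, with adjusted p = 0.537, 0.580, 0.537 and 0.614 with an estimated correlation. Exact relabelling of the arrays' list means gave two-sided p of 0.0310, 0.137, 0.0598 and 0.151 (adjusted p = 0.209, 0.353, 0.209 and 0.353 over 14 array measures). No member of the 4 lists passed over all genes or when adjusted over the list alone. Obp56d, an odorant-binding protein gene, stood at 0.71 (adjusted p = 0.145) and Mlc2, a muscle myosin light chain gene, at 0.24 (adjusted p = 0.316). At 4 h the cuticle list was lower in deprived brains (median -0.06, camera adjusted p = 0.00205; adjusted p = 0.768 with an estimated correlation), unlike at 2 h (0.09) and 6 h (0.14), and within wash run 2 at 4 h its median was 0.02. Photoreceptor markers were lower (14 genes, median -0.13, camera adjusted p = 0.00962, and adjusted p = 0.537 with an estimated correlation), with trp at -0.49 (adjusted p = 0.274) and Arr1 at -0.45 (adjusted p = 0.314). Their median was 0.07 among the 4 h arrays of wash run 2. It was -0.01 and -0.24 within wash runs 2 and 3, at unmatched hours, and -0.03 and -0.23 within chip lots 2 and 3. Gut and salivary (camera adjusted p = 0.0626), haemocyte (0.601), fat body (0.601) and glial (0.601) markers did not pass; haemocyte markers had a positive median while their mean was -0.02 and their test pointed down. In the glial list wrapper stood at -0.27 (adjusted p = 0.0546) and was lower when adjusted over the list alone. The 3' to 5' control difference of GAPDH was 0.23 log2 units higher in deprived arrays (exact permutation p = 0.0278, two-sided; adjusted p = 0.209 over 14 array measures).

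Camera with a preset correlation of 0.01 thus called 20 of 34 lists, 10 in each direction. Over all probe sets the median difference was 0.03 in the dimmest decile of signal level and -0.04 in the brightest. With an estimated correlation it called 0, with 5 at an unadjusted p under 0.05, and fry, which tests each list by itself, called 5: activity-regulated genes, antimicrobial peptides, aminoacyl-tRNA synthetases, ribosome biogenesis and heat shock proteins. With the 3' to 5' control difference as a covariate, or with the dimmer genes left out, 12 lists passed. The covariate ended the calls of the synaptic vesicle, ion channel, receptor, fly sleep, P450, glutathione, photoreceptor and ovary lists. Leaving out dim genes ended those of the same lists except glutathione, and those of ribosome biogenesis and mitochondrial ribosomal proteins. Quantile normalisation ended the channel, receptor, fly sleep, mitochondrial ribosomal and ovary calls, and cyclic loess the first 4 of these. The wash run block ended the receptor, glutathione and photoreceptor calls, as did the omission of wash run 4, which also ended the channel call.

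**Figure D2:**
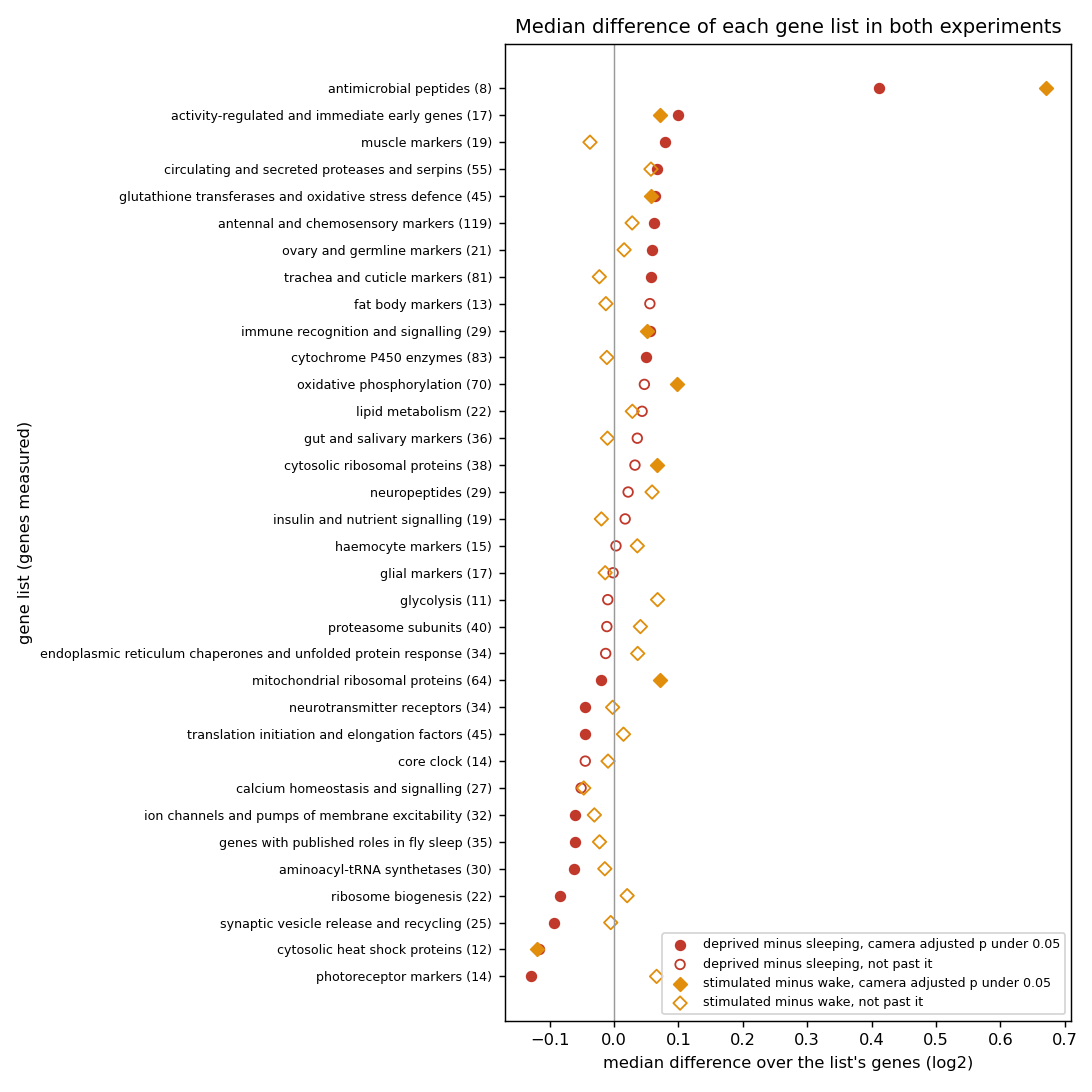
Median log2 difference over the measured genes of each fixed list for deprived minus sleeping flies (circles) and stimulated minus wake flies (diamonds), filled where the camera adjusted p is under 0.05 with the preset correlation. The antimicrobial peptide list lies farthest to the right in both, at 0.41 and 0.67.

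Taken hour by hour, sr was the transcript that passed at every time. It was higher by 2.14 ± 0.163 at 2 h (adjusted p = 6.60e-07), by 1.49 at 4 h (adjusted p = 0.000269) and by 1.19 at 6 h (adjusted p = 0.00366), in 3 of 3 deprived arrays each time. It was the 1 probe set called at 2 h, and at 4 h aay was called beside it (0.93 ± 0.145, adjusted p = 0.0226; 3 of 3). At 6 h 13 probe sets passed, 8 higher and 5 lower. CG13315 (1.19, adjusted p = 0.0381), the tetraspanin gene Tsp42Ed (0.67, adjusted p = 0.0410), Cyp6a8 (0.62, adjusted p = 0.0350) and slf (0.57 ± 0.0799, adjusted p = 0.00366) rose in 3 of 3 deprived arrays. CAH7 (-0.77 ± 0.112, adjusted p = 0.00554), RhoGAP102A (-0.76, adjusted p = 0.0318), hoe1 (-0.54, adjusted p = 0.0410) and the chaperone gene Hsp110 (-0.53, adjusted p = 0.0410) fell in 3 of 3. At 4 h, 611 of 13966 probe sets had an unadjusted p under 0.05, below the share of 0.05 that chance alone would give. With wash run as a block, 0 probe sets passed at 4 h in limma. The difference of sr was then 1.10 (adjusted p = 0.0723) at 4 h and at 0.66 (adjusted p = 0.0730) at 6 h. That block called 704 probe sets at 6 h. All sleeping 6 h arrays were in wash run 2, and the deprived 6 h arrays were in wash runs 3 and 4. Wash run 3 was tied to wash runs 2 and 4 only through the deprived 6 h arrays. The offset of wash run 4 came from deprived arrays alone. The 704 calls and the 6 h value of sr under the block therefore rest on deprived 6 h replicate 3. In the main fit the 6 h count was 4 without deprived 6 h replicate 1 or 3.

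Over all probe sets the median difference depended on signal level, at -0.02 in the dimmest decile and 0.07 in the brightest at 4 h, against 0.04 and -0.08 at 2 h and 0.07 and -0.10 at 6 h. Of lists that did not pass in the mean, oxidative phosphorylation was higher at 4 h (70 genes, median 0.15, camera adjusted p = 2.13e-07; adjusted p = 0.608 with an estimated correlation). Wash run 2 held 1 deprived and 2 sleeping arrays of that hour, and within it the median was -0.10. Mitochondrial ribosomal proteins had a median of -0.10 at 2 h, 0.08 at 4 h and -0.08 at 6 h, and of -0.13 within wash run 2 at 4 h. They had camera adjusted p of 3.13e-05, 4.76e-05 and 0.00176 and adjusted p = 0.650, 0.768 and 0.668 with an estimated correlation. The activity-regulated list at 4 h was the call that held with an estimated correlation (17 genes, median 0.12, camera adjusted p = 1.41e-06; adjusted p = 0.0492 with an estimated correlation). It did not pass by fry (adjusted p = 0.0556), and within wash run 2 at 4 h its median was 0.06. Endoplasmic reticulum chaperones had a median of -0.08 at 2 h and 0.11 at 4 h (camera adjusted p = 0.000691 and 0.000559; adjusted p = 0.585 and 0.485 with an estimated correlation), and of -0.00287 within wash run 2 at 4 h. Ribosome biogenesis genes were lower at 6 h (median -0.21, camera adjusted p = 7.57e-06; adjusted p = 0.163 with an estimated correlation), and 8 of 22 were lower when adjusted over the list alone.

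For the change in the deprivation effect between 2 and 6 h, 463 of 13966 probe sets had an unadjusted p under 0.05. This is below the share of 0.05 that chance alone would give. In limma the adjusted threshold called 1 probe set. That probe set is paired with several gene symbols and is not named here; its difference moved from 0.20 at 2 h to -1.07 at 6 h, a change of -1.26 ± 0.187 (adjusted p = 0.0251). Among named genes the smallest p-values belonged to CG7860 (0.93), Actn (0.45), Mat89Ba (-0.54), CG6465 (-0.59) and sr (-0.95), which did not pass (adjusted p = 0.999 each). The call ended when each of 9 of the 12 arrays was left out in turn, and under the replicate, chip lot and wash run blocks. Of the lists, ribosome biogenesis (median -0.16) and activity-regulated genes (median -0.15) were lower at 6 h than at 2 h relative to sleeping flies, with camera adjusted p of 0.00142 and 0.0101 and adjusted p = 0.477 each with an estimated correlation. Camera called 10 of the 34 lists.

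The 0 h point allowed the direction of change to be followed from ZT14. In sleeping flies 15 probe sets had a linear trend, 13 upward and 2 downward. The steepest rises per hour were in Acsx3, named as an acyl-CoA synthetase (0.45 ± 0.0317, adjusted p = 8.44e-08), and CG10513 (0.40 ± 0.0203, adjusted p = 4.08e-10). Phyhd1 (0.26, adjusted p = 3.59e-06), Ugt35B1, a UDP-glycosyltransferase gene (0.24, adjusted p = 1.38e-05) and CG10514 (0.21, adjusted p = 1.19e-05) followed. The clock transcription factor gene vri fell by 0.16 per hour (adjusted p = 3.65e-05), and Actn, the alpha-actinin gene, fell by 0.07 (adjusted p = 0.0286). In deprived flies 41 probe sets had a trend, 13 upward and 28 downward. The rises were led by 4 of the same genes: CG10513 (0.35, adjusted p = 6.41e-09), Acsx3 (0.34, adjusted p = 1.02e-05), Ugt35B1 (0.18, adjusted p = 0.000798) and Phyhd1 (0.17, adjusted p = 0.00107), followed by sr (0.15, adjusted p = 0.0111). The level of sr was 6.13 at 0 h and 8.25, 7.60 and 7.33 at 2, 4 and 6 h, so its upward slope comes from the 0 h point. CAH7 fell by 0.18 per hour (adjusted p = 2.81e-05), the chloride channel gene ClC-a fell by 0.16 (adjusted p = 0.00242), and vri fell by 0.16 (adjusted p = 0.000105). Gclm, the modifier subunit of glutamate-cysteine ligase, fell by 0.12 (adjusted p = 0.0221) and speck, an arylalkylamine N-acetyltransferase gene, fell by 0.11 (adjusted p = 0.000159). Each trend rests on 12 arrays, and both share the ZT14 arrays. With wash run as a block the sleeping trend kept 1 call, CG10513 (0.46, adjusted p = 0.000963), while vri stood at -0.17 (adjusted p = 0.582).

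Of the 68 probe sets higher in deprived brains, 48 rose over deprivation at an unadjusted p under 0.05, and of the 61 lower ones 45 fell. These probe sets were chosen on the same deprived arrays, which favours a trend in the chosen direction, so the counts are no independent evidence. Across the 129, 78 had such a trend in deprived flies alone, 13 in sleeping flies alone, 17 in both and 21 in neither, counts that come from separate tests and not from a test of the difference between trends. Among the lists, 8 passed for the sleeping trend and 13 for the deprived trend by camera, and 0 with an estimated correlation (1 and 1 at an unadjusted p under 0.05); fry called 0 in both. Mitochondrial ribosomal proteins were lower with time in sleeping flies (median -0.02 per hour, camera adjusted p = 5.88e-07; adjusted p = 0.919 with an estimated correlation) and in deprived flies (-0.03, camera adjusted p = 2.14e-07; adjusted p = 0.775 with an estimated correlation). Endoplasmic reticulum chaperones were lower in sleeping flies (camera adjusted p = 4.90e-05; adjusted p = 0.919 with an estimated correlation), where CaBP1 alone was lower when adjusted over the list alone (-0.07, adjusted p = 0.117 over all genes).

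The second experiment asked what handling alone does in flies that are awake anyway. Among named genes past the threshold the largest rise was again in sr, higher by 1.15 ± 0.119 (adjusted p = 0.00142) in stimulated than in wake flies. BomS2 rose by 1.06 ± 0.148 (adjusted p = 0.0182), and CG42807 by 0.82 ± 0.127 (adjusted p = 0.0286). CG13315 rose by 0.74 ± 0.112 (adjusted p = 0.0283) and Ect3, a beta-galactosidase gene, by 0.62 ± 0.107 (adjusted p = 0.0426), each in 3 of 3 stimulated arrays. In all, 12 probe sets passed in limma, 11 higher and 1 lower, with 982 at an unadjusted p under 0.05 and 9 by the Fs test. The number was 1 to 5 when any single array was left out, the lowest without wake replicate 2, where sr still passed, and 5 with the 3' to 5' control difference as a covariate. All 9 arrays were scanned on 1 day, 8 came from chip lot 3, and wash run was not analysed for them.

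All 8 antimicrobial peptide genes had a positive difference between stimulated and wake flies, with a median of 0.67 (camera adjusted p = 2.33e-06; adjusted p = 0.376 with an estimated correlation). None passed over all genes and 4 did when adjusted over the list alone, with DptB at 1.71 (adjusted p = 0.362), Mtk at 1.17 (adjusted p = 0.260) and Drsl5 at 0.88 (adjusted p = 0.0662). Of 29 immune recognition genes BomS2 rose and 6 were higher when adjusted over the list alone, PGRP-SB1 standing at 1.17 (adjusted p = 0.0566) and Rel at 0.45 (adjusted p = 0.415). As a group they were higher (camera adjusted p = 0.000427; adjusted p = 0.376 with an estimated correlation). Of 17 activity-regulated genes sr rose and 4 were higher when adjusted over the list alone, with cbt at 0.38 (adjusted p = 0.257); the list was higher (camera adjusted p = 0.00547; adjusted p = 0.443 with an estimated correlation). The list of 12 cytosolic heat shock protein genes was lower (median -0.12, camera adjusted p = 0.0105; adjusted p = 0.376 with an estimated correlation), with none passing and DnaJ-1 at -0.36 (adjusted p = 0.610). Oxidative phosphorylation (70 genes, median 0.10), mitochondrial ribosomal proteins (64, 0.07), cytosolic ribosomal proteins (38, 0.07) and glutathione genes (45, 0.06) were higher. They had camera adjusted p of 5.17e-05, 0.00495, 0.0105 and 0.0350 and adjusted p = 0.869, 0.927, 0.911 and 0.821 with an estimated correlation. Fry called 0 of the 34 lists, and with the 3' to 5' control difference as a covariate 3 of the 8 lists passed, the antimicrobial, immune recognition and activity-regulated ones. The heat shock, oxidative phosphorylation, cytosolic ribosomal and glutathione calls ended there (adjusted p = 0.0665, 0.230, 0.223 and 0.149), and the test of mitochondrial ribosomal proteins turned down (adjusted p = 0.772, median 0.02). Without wake replicate 1 the same 5 calls ended, and the mitochondrial ribosomal test again pointed down. Photoreceptor markers, outside the 8, were higher with the covariate (median 0.17, camera adjusted p = 2.33e-05), against an adjusted p of 0.243 without it. The mean of the 3 control differences was 0.26 log2 units higher in stimulated arrays (exact permutation p = 0.3, where the smallest possible two-sided p is 0.1). Glial and fat body markers had medians of -0.01 each with means and tests that pointed up (camera adjusted p = 0.913 and 0.932), and 2 glial genes, Indy and alrm, were higher when adjusted over the list alone.

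Handling was then set against deprivation. Of the 31 probe sets of the F test, 16 differed between stimulated and wake flies at an unadjusted p under 0.01, 12 higher and 4 lower, where 0.31 would be called by chance. Of the 31, 30 had the sign of the deprivation difference. Of the 129 probe sets of the mean, 44 did so, 34 higher and 10 lower, and 111 shared the sign: 62 of the 68 higher and 49 of the 61 lower. Past the adjusted threshold in both were 9 probe sets, 8 higher and 1 lower, where independent lists would share 0.0536 and 0.00437; sr, BomS2, CG13315, CG5966, BomS5 and CG1572 were among them. The 2 experiments share no arrays. Across probe sets, which are not independent replicates, the differences correlated with r = 0.456 for the mean and 0.544 for 4 h. A direct test of the 4 h deprivation effect against the stimulation effect called 0 probe sets in limma, with 246 at an unadjusted p under 0.05. Of 13966 tested, 246 is below the share of 0.05 that chance alone would give. The named genes with the smallest p were Acsx2 (-0.72), Cpr72Ec (-0.61), kumpel (-0.39), CG10700 (-0.38) and Tsp42Ep (-0.34), none past the threshold (adjusted p = 1.00 each). That test does not show that the effects are alike, since an added change of 0.5 log2 units was recovered for 50% of probe sets in data simulated for this contrast and a change of 1 for 90%. By camera the photoreceptor (median -0.21) and antennal (-0.06) lists were lower under deprivation than under stimulation (camera adjusted p = 0.0191 each; adjusted p = 0.837 each with an estimated correlation).

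**Figure D3:**
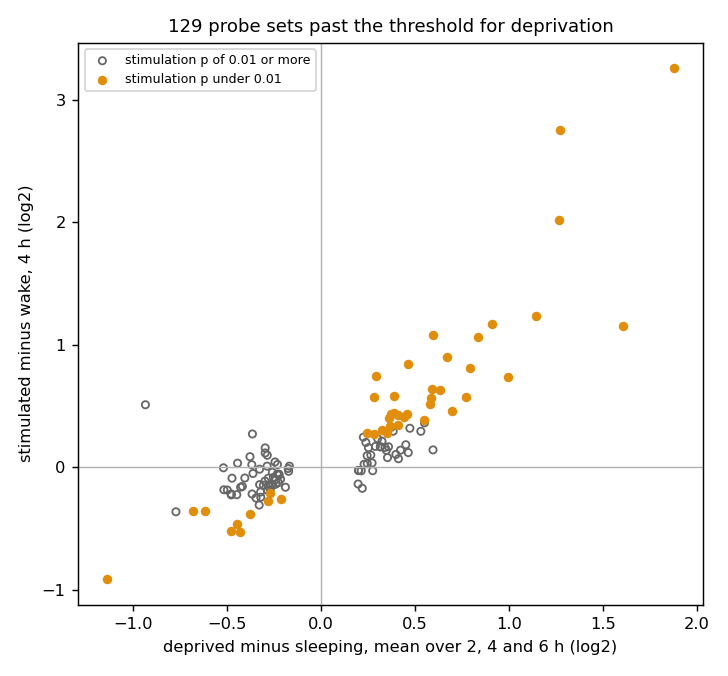
Log2 difference of stimulated minus wake flies (vertical) against deprived minus sleeping flies (horizontal, mean over 2, 4 and 6 h) for the 129 probe sets past the threshold for deprivation; filled points have an unadjusted p under 0.01 for stimulation. Of the points 111 lie on the same side of 0 on both axes and 44 are filled.

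The late active period was followed in undisturbed flies from ZT10 to ZT14. Ugt35B1 and CG10513 fell by 1.55 each (SE 0.108 and 0.145; adjusted p = 8.40e-06 and 0.000211), and sr fell by 0.88 ± 0.119 (adjusted p = 0.00810). The ebony gene e, which acts in beta-alanyl-dopamine synthesis, fell by 0.66 ± 0.0777 (adjusted p = 0.00234) and Pcyt2, a gene of phosphatidylethanolamine synthesis, fell by 0.63 ± 0.0849 (adjusted p = 0.00810), and all 5 were lower in 3 of 3 wake arrays. In limma 9 probe sets passed, all lower at ZT14, and 1591 had an unadjusted p under 0.05; the count was 3 without wake replicate 2 or without ZT10 replicate 3, and 4 without ZT10 replicate 1. This comparison shares the wake arrays with the stimulation comparison.

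All 13 fat body markers had a positive difference between ZT14 and ZT10, with a median of 0.37. None passed over all genes and 8 did when adjusted over the list alone (camera adjusted p = 2.77e-09; adjusted p = 0.340 with an estimated correlation). Among them were fit (0.99, adjusted p = 0.119), the yolk protein genes Yp3 (0.81, adjusted p = 0.326) and Yp1 (0.71, adjusted p = 0.348), and Lsp2 (0.41, adjusted p = 0.0920). Over all probe sets the median difference was 0.04 in the fifth decile of signal level and -0.09 in the brightest. Mitochondrial ribosomal proteins were lower (64 genes, median -0.12, camera adjusted p = 2.77e-09; adjusted p = 0.378 with an estimated correlation). So were translation factors (45, median -0.12, camera adjusted p = 4.96e-05; adjusted p = 0.340 with an estimated correlation) and oxidative phosphorylation (70, median -0.11, camera adjusted p = 0.000121; adjusted p = 0.435 with an estimated correlation). Activity-regulated genes were lower (17 genes, camera adjusted p = 0.0145; adjusted p = 0.378 with an estimated correlation), with sr the 1 that fell and 6 lower when adjusted over the list alone. Trachea and cuticle markers were higher (median 0.08, camera adjusted p = 0.000445) and photoreceptor markers lower (median -0.07, camera adjusted p = 0.0128), both with adjusted p = 0.378 with an estimated correlation. Camera called 17 of the 34 lists, 3 higher and 14 lower; with an estimated correlation it called 0, with 4 at an unadjusted p under 0.05, and fry called 0.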

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

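The tests of level-dependent differences, wash run, 3' to 5' control signal, fat body transcripts and stimulation were chosen after the results they bear on were seen, while those of antennal tissue, cuticle and muscle and the regroupings of arrays were set before.

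A probe set paired with several symbols stood out because its deprivation effect differed between 2 and 6 h by an interaction test, with a change of -1.26 (SE 0.187, adjusted p = 0.0251). As many calls came from 11 of 100 regroupings of arrays between 2 and 6 h, with 56 as the highest other count, so chance is not excluded for that count of 1.

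Antimicrobial peptide genes were higher in deprived brains by camera with the preset correlation (adjusted p = 0.203 with an estimated correlation). Fat body is a main source of these peptides and could be carried over. Over the deprivation experiment the mean difference of its markers minus that of the peptides was -0.396 (SE 0.121). On average the markers thus rose less than the peptides. The markers went both ways, with Yp1 at -0.15 (SE 0.241), Yp3 at 0.12 (SE 0.304) and fit at 0.80 (SE 0.245). Within wash run 3 and among the 4 h arrays of wash run 2 the markers' medians (0.14 and 0.15) exceeded those of the peptides (0.09 and 0.12). They were lower within wash run 2 (0.08 against 0.32) and chip lots 2 and 3 (-0.01 and 0.12 against 0.19 and 0.54). Carry-over of fat body is therefore left open. With run as a block the list still passed with the preset correlation (camera adjusted p = 0.0185). Its median then went from 0.41 to 0.20. The block assumes that run effects add, and at 2 and 6 h run and condition divide the arrays in the same way. Wash run is therefore left open as well. Handling stays open: the list was also higher in flies stimulated in their active period (adjusted p = 2.33e-06 with the preset correlation; adjusted p = 0.376 with an estimated correlation). A candidate explanation is thus stimulation apart from sleep loss, as a hypothesis found and tested on the same data.

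Cytosolic heat shock protein genes were lower in deprived brains. The list passed with the 3' to 5' control signal as a covariate (camera adjusted p = 0.00996) and with wash run as a block (camera adjusted p = 0.00673). These calls rest on the preset correlation, and at 2 and 6 h wash run and condition divide the arrays in the same way. RNA quality seen in the control signal and wash run are therefore not excluded. The median of the list was -0.14 and -0.06 within chip lots 2 and 3. It was -0.05 and -0.13 within wash runs 2 and 3, at unmatched hours. Among the 4 h arrays of wash run 2 it was -0.09, against -0.12 in the main fit. The list was also lower in stimulated flies (adjusted p = 0.0105), so an effect of stimulation apart from sleep loss may be part of it, though that call ended without wake replicate 1 and with the covariate (adjusted p = 0.0665), where the median went from -0.12 to -0.10. With an estimated correlation neither the deprivation call (adjusted p = 0.203) nor the stimulation call (adjusted p = 0.376) held.

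Antennal, cuticle and muscle marker lists were higher in deprived brains by camera with the preset correlation, but not by fry, with an estimated correlation (adjusted p = 0.537, 0.580 and 0.537) or by exact relabelling of the arrays' list means (adjusted p = 0.209, 0.353 and 0.209). The highest camera adjusted p of the 3 lists was 0.0136 after cyclic loess and 0.000984 with wash run as a block. Both values used the preset correlation, the only setting of the test in which the lists were called. They therefore do not exclude level-dependent differences between arrays or wash run. Within the run shared at 4 h by 1 deprived and 2 sleeping arrays the medians were 0.01, 0.02 and 0.19. Carried-over tissue would raise its abundant transcripts, so the brightest members of each list, ranked on these brain arrays, were examined. They were higher by 0.125 (SE 0.0464) for the antennal list and 0.0916 (SE 0.0412) for the muscle list, as carry-over in dissection would give. For the cuticle list the value of 0.0691 (SE 0.0389) leaves it open. The other members were higher by 0.0520 (SE 0.0281), 0.0788 (SE 0.0447) and 0.0545 (SE 0.0323) in that order. The lists had been called higher on these same arrays, which favours positive values, so this does not single out carry-over. Members of the 3 lists also varied together across arrays of a group, with mean residual correlations of 0.234, 0.366 and 0.223, above those of matched random lists. Carry-over may underlie the antennal and muscle calls but was not told apart from other causes, and no biological explanation was tested.

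The rule set before asked that under 0.05 of the groupings of the arrays, the real one included, call as many. It was met by the 129 calls of the mean (2 of 100 as large, highest other 234) and the 31 of the F test (2 of 100, highest other 355). The 15 of the sleeping trend (1 of 100, highest other 10) and the 41 of the deprived trend (2 of 100, highest other 114) met it too. For the mean, the F test and the deprived trend another grouping called more than the real one, so chance is not excluded there. The regroupings of the sleeping trend did not hold wash run, and with wash run as a block that trend kept 1 call. The 20 lists of the mean did not meet the rule (5 of 100, highest other 22). For the direct test of deprivation against stimulation, with 0 calls, every regrouping is as large by construction (100 of 100, highest other 67), which says nothing about chance. With 6 arrays the 10 splits are too few for a share under 0.05. The real and highest other counts were 1 and 67 at 2 h (2 of 10 as large), 2 and 0 at 4 h (1 of 10), 13 and 0 at 6 h (1 of 10), 12 and 0 for stimulated minus wake (1 of 10), 16 and 1 for stimulation within the deprivation set (1 of 10), 9 and 1 for wake minus ZT10 (1 of 10), and 8 and 12 for the lists of stimulated minus wake (2 of 10). Splits that call several times the real count may reflect a structure of the samples other than deprivation, which was not tested. At 2 h the 67 came from exchanging deprived replicate 2 with sleeping replicate 3. That split parts the arrays by mean 3' to 5' control difference (2.05, 2.50 and 2.67 against 1.82, 1.82 and 1.84). At 4 h the split that follows wash run called 0, and at 2 and 6 h wash run and condition divide the arrays in the same way.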

How the results depend on the processing

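Cyclic loess, the 3' to 5' covariate, the omission of wash run 4 and, for the gene lists, the chip lot and wash run blocks were chosen after seeing the data; the other settings were planned. Of 38 named genes past the threshold in the mean, 12 passed in every other setting, 18 passed without each array and 0 changed sign; the 12 are sr, CG13315, aay, CG16772, CG1572, Rel, Lip4, fne, CAH7, Stip1, CG1416 and DnaJ-1. Arrays with their own weights (0.267 to 6.80) or fewer residual degrees of freedom change the spread; for the other changes given here the cause was not tested.

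For the mean, 129 became 206 with all 30 arrays in the fit, 1157 with array weights, 72 with a wash run block, 58 without wash run 4 and 216 at a threshold of 0.10. For the F test, 31 became 85 with all 30 arrays, 3095 with weights, 19 with a chip lot block, 50 with a wash run block, 87 by Fs, 16 without wash run 4 and 82 at 0.10. At 2 h, 1 became 429 with weights and 3 with the covariate. At 4 h, 2 became 8 with only the groups compared, 10 with all 30 arrays, 1949 with weights, 1 with a chip lot block, 0 with a wash run block and 4 with the covariate. At 6 h, 13 became 25 with quantile normalisation, 120 with only the groups compared, 70 with all 30 arrays, 447 with weights, 6 with a chip lot block and 704 with a wash run block. Those 704 calls rest on deprived 6 h replicate 3, as given above. The sleeping trend, 15, became 24 with only the groups compared, 28 with all 30 arrays, 797 with weights, 1 with a wash run block and 25 with loess. The deprived trend, 41, became 18, 93 and 1637 with the first 3 of these, and its 13 higher and 28 lower calls became 16 and 19 with quantile normalisation and 18 and 18 with loess. The change from 2 to 6 h, 1, became 0 with quantile normalisation, only the groups compared, chip lot or wash run blocks or loess, and 28 with weights; with 1 probe set per gene the called probe set, which has several symbols, was not tested, and 0 were called. Stimulated minus wake, 12, became 35 with only the groups compared, 2 with all 30 arrays and 5 with the covariate. Wake minus ZT10, 9, became 5 with dim probe sets left out, 14 with median centring or with trended and robust variance, 16 with 1 probe set per gene and 40 with the covariate. Stimulation within the deprivation set, 16, became 25 with all 30 arrays and 170 with weights. The 20 lists of the mean became 0 with an estimated correlation, 5 by fry and 12 with dim genes left out or with the covariate, and their 10 higher and 10 lower calls became 10 and 6 with quantile normalisation and 12 and 6 with loess. The 8 lists of stimulated minus wake became 0 with an estimated correlation, 0 by fry and 4 with the covariate, 3 of them among the 8. The direct test of deprivation against stimulation kept 0 calls in each setting.

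The list of mitochondrial ribosomal proteins, stimulated minus wake in the active period, turned direction in the test, though not in its median, with the covariate (adjusted p = 0.772) and without wake replicate 1 (adjusted p = 0.990, against a lowest of 4.11e-07 without another array).

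The replicate block called 98 probe sets for the mean, 97 of them among the 129, 1 at 4 h and 0 for the change from 2 to 6 h, and moved no other count by over 1.5 times. Same-numbered deprived and sleeping arrays correlated between -0.380 and 0.439 in their deviations from group means, over 0.1 in 5 of 9 pairs, and 4 of 9 correlated best with their own number; for stimulated and wake arrays 0 of 3 pairs were over 0.1. These correlations do not settle whether the numbers pair the samples, and the main fits used no pairing.

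Without 1 array, the mean ranged from 66 to 189: 85 without deprived 4 h replicate 3, 81 without deprived 6 h replicate 3, 78 and 77 without sleeping 2 h replicates 1 and 3, 66 and 79 without sleeping 4 h replicates 1 and 3, and 81 and 72 without sleeping 6 h replicates 1 and 3. The F test ranged from 21 to 74, with 51 and 74 without deprived 2 h replicates 1 and 2. At 2 h the range was 1 to 5, with 5 without deprived replicate 2. At 4 h it was 1 to 4, with 4, 4 and 1 without deprived replicates 1, 2 and 3 and 1 without each sleeping replicate. At 6 h it was 4 to 15, with 4, 6 and 4 without deprived replicates 1, 2 and 3 and 8 and 5 without sleeping replicates 1 and 3. The sleeping trend gave 13 to 17. The deprived trend gave 17 to 75, with 17, 18 and 62 without 0 h replicates 1, 2 and 3, 75 without deprived 2 h replicate 1, and 19 and 23 without deprived 6 h replicates 1 and 3. The change from 2 to 6 h gave 0 to 1, with 0 without deprived 2 h replicates 2 or 3, deprived 6 h replicates 2 or 3, sleeping 2 h replicates 1 or 2, or any sleeping 6 h replicate. Stimulated minus wake gave 1 to 5, with 3, 2 and 5 without stimulated and 5, 1 and 2 without wake replicates 1, 2 and 3. Wake minus ZT10 gave 3 to 9, with 3 without wake replicate 2 and 4 and 3 without ZT10 replicates 1 and 3. Stimulation within the set gave 12 to 27, with 26 and 27 without deprived 2 h replicates 1 and 2. The lists gave 14 to 23 for the mean and 6 to 14 for stimulated minus wake, 14 without wake replicate 2. Leaving an array out leaves 2 in its group, and the spread is then shared with the other groups.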

Other observations

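CG10513 and Ugt35B1 followed the hour in both experiments. CG10513 stood at 5.43 at ZT10 and 3.88 in wake flies at ZT14, and in the other experiment at 3.91 at ZT14, 4.02 in sleeping flies at ZT18 and 6.54 at ZT20, with 6.11 in deprived flies at ZT20. Ugt35B1 stood at 8.29 at ZT10, 6.74 in wake flies and 6.67 at ZT14, and at 8.15 in sleeping and 7.77 in deprived flies at ZT20. The clock gene vri fell from 6.77 at ZT14 to 5.83 in sleeping and 5.80 in deprived flies at ZT20 and stood at 6.37 at ZT10. Acsx3 reached 8.11 in sleeping and 7.16 in deprived flies at ZT20 from 5.36 at ZT14, and stood at 5.19 at ZT10. Levels are set side by side here across the experiments and were not tested across them.

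Some of the largest differences belong to probe sets with no single symbol, chosen here for their size after their values were seen. The largest rise among them was 1.88 ± 0.377 in deprived flies (adjusted p = 0.0189). That probe set stood at 3.26 ± 0.715 in stimulated minus wake flies and did not pass there (adjusted p = 0.220). The largest fall was -1.14 ± 0.147 (adjusted p = 0.000558), at a probe set that stood at -0.91 ± 0.172 with stimulation and did not pass there (adjusted p = 0.0740). At 4 h, lipid metabolism (median 0.15), glycolysis (0.11) and neuropeptide genes (0.07) were higher in deprived flies, with camera adjusted p of 0.00132, 0.0192 and 0.0390 and adjusted p = 0.657, 0.485 and 0.295 with an estimated correlation. Within wash run 2 at that hour, with 1 deprived and 2 sleeping arrays, the medians were 0.21, 0.06 and 0.02.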
